A study of Mus musculus with 7 samples.

How the data were processed

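CD4+ T cells were selected with magnetic beads (biotin-coupled antibody to CD4, streptavidin beads, positive selection) from draining lymph nodes of EAM mice (4 arrays) and LAD mice (3 arrays). Per the labels, RNA was extracted with a miRVANA kit and 100 ng of total RNA per array was labelled with Cy3 at its 3′ end. Per the file headers, the 7 one-colour Agilent arrays lay on 1 slide and were read by Agilent Feature Extraction 10.7.3.1. Slide columns held 1 group each, so column and group cannot be told apart. The deposited scanner files give intensity per spot (mean spot signal, local background and background-subtracted signal, none scaled between arrays), intensity per miRNA as total gene signal, and other columns that are 0 or 1 marks of detection, saturation and spot quality. The authors' value table is in log2 units, 1 value per miRNA name; the submitters' notes name RMA, with no version and no role. Its values were close to quantile-normalized log2 signal without background correction (Pearson's r across values 0.999, 97.9% within 0.1).

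Each array held 58594 spots, of which 56430 were not controls, for 4415 probes and 1881 miRNA names. Mean spot signal was background-corrected with the normexp model of limma 3.58.1 in R 4.3.3 (foreground only, no offset), quantile normalized between arrays, log2 transformed, summarized as the median of the replicate spots of a probe with spots marked as outliers left out, and then by median polish over the probes of a miRNA. Values are log2 units of this signal unless called unscaled. Files were read with the R package data.table, version 1.17.8. miRNAs detected on every array of at least 1 group were tested, which gave 423. The 75th percentile of signal per array ranged from 124 to 1071 intensity units, and the number of arrays limits the precision.

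The groups were compared with limma (lmFit and eBayes) and Benjamini-Hochberg adjusted p values, with 0.05 as the threshold and the difference as EAM minus LAD. The fit takes 1 variance per miRNA for both groups. Where the smaller LAD group varies more, its standard errors and p values can be too small. Where a miRNA was detected on no array of 1 group, its fold is given as a lower bound that holds for the background-corrected, quantile-normalized values only. Each array of that group was set to the larger of its own value and the lowest value of any miRNA detected on it. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01 where at least 3 members were tested, and with an estimated correlation and fry as alternatives. Per-array measures were compared with two-sided exact permutation tests over 35 splits. The groups, tests, lists and most alternatives were chosen before the data were examined. So was the rule for named miRNAs: among those that passed with no overlap between the groups, the 12 with the largest fold in each direction, up to 4 members with the smallest p per list, markers of other cell types detected on all 7 arrays, and miR-721, miR-155-5p, miR-146a-5p, miR-21a-5p, miR-150-5p and miR-181a-5p. Of the 68 named miRNAs, 62 were found in the RefSeq table of assembly GRCm38.p6, used for names and host genes only, and 48 had a position in the array design (mm9).

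The alternatives were no background correction, normexp with local background and an offset of 50, scaling to the 75th percentile (of all probes, or of the 303 probes detected on all arrays), median centring, no scaling, total gene signal, the authors' table, other detection filters, other variance models and array weights, the replicate number as a block, leaving out each array, a fold threshold and an unmoderated unequal-variance test. The test was tried on simulated data with 100 of 423 miRNAs changed, in 20 simulations: it recovered 36.9%, 70.0% and 95.9% of log2 changes of 0.585, 1 and 2, with 2.85 false calls on average. In 50 simulated lists of each kind, camera called 50 that were shifted and 0 that were not. The simulated noise was independent, with the same SD in both groups, and with 1 common SD for the lists. The real LAD arrays varied more than the EAM arrays, so these rates need not hold for this comparison. The 130 miRNAs detected on some arrays but not on every array of a group were left out of the tests.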

Results

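MicroRNA (miRNA) signal was measured on 7 arrays of CD4+ T cells, the helper cells of adaptive immunity, taken from the lymph nodes that drain the affected tissue of mice. EAM, a model of myocarditis, gave 4 arrays, and LAD, a model of myocardial infarction, gave 3. The sample labels put the EAM cells at day 6 after induction and the LAD cells at day 3, while the series text gives the days in the opposite order. No cells of healthy mice were measured, so each difference is one between the models, and model, day and slide column changed together. The array carried 1881 miRNA names, of which 553 were detected on at least 1 array and 251 on all 7.

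More miRNAs were detected in the EAM cells than in the LAD cells. The EAM arrays detected 445 to 471 miRNAs and the LAD arrays 311 to 380. The mean was 458 ± 10.74 (SD, n = 4) in EAM and 344 ± 34.6 (SD, n = 3) in LAD (two-sided exact permutation p = 0.0571, the smallest that 35 splits allow). The 75th percentile of the unscaled signal was 9.84 ± 0.18 (log2, SD, n = 4) in EAM and 7.84 ± 1.03 (SD, n = 3) in LAD, a 3.99-fold difference (two-sided exact permutation p = 0.0571). The spiked-in control RNAs had a log2 signal of 12.83 ± 0.18 in EAM and 13.07 ± 0.03 in LAD. The LAD arrays also differed more among themselves: pairs of EAM arrays correlated across miRNAs at 0.992 to 0.998, and pairs of LAD arrays at 0.893 to 0.967 (Pearson's r; miRNAs are not independent replicates).

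**Figure D1:**
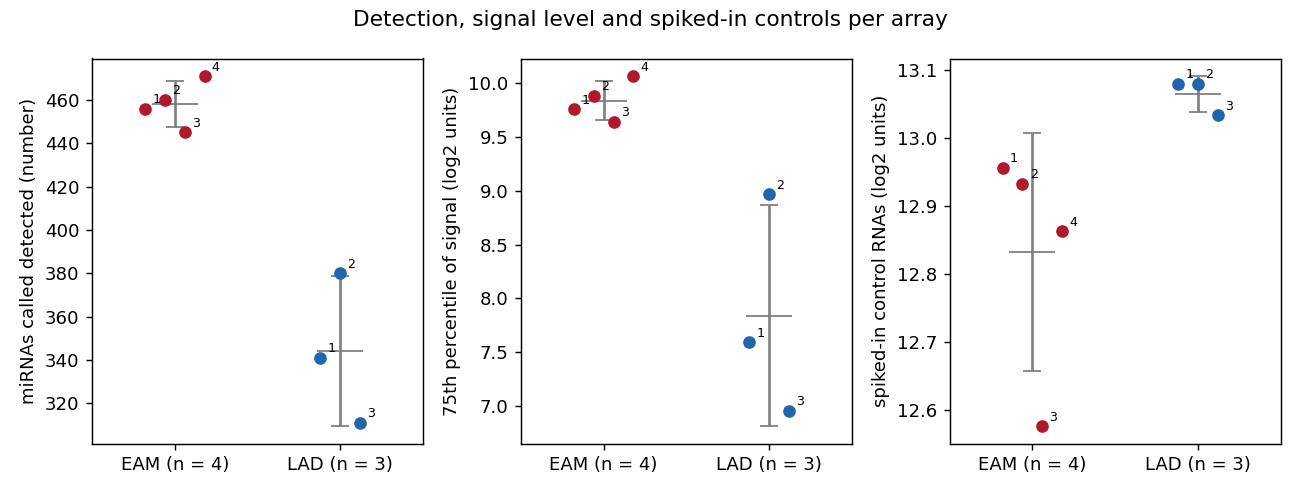
Number of detected miRNAs (left), 75th percentile of the unscaled signal (middle, log2) and signal of the spiked-in control RNAs (right, log2) for each array, numbered by replicate; horizontal lines are means and bars are 1 SD. The 4 EAM arrays detected 445 to 471 miRNAs and the 3 LAD arrays 311 to 380.

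The comparison asks which miRNAs differ between CD4+ T cells of the myocarditis model and those of the infarction model. EAM cells had higher levels of miR-101a-3p and miR-101c, of miR-29a-3p, miR-29b-3p and miR-29c-3p, and of miR-146a-5p, miR-690, miR-3473a and miR-3473b. In the background-corrected values the largest difference toward EAM was in miR-101c, with a quantile-normalized log2 signal of 7.84 ± 0.27 (SD, n = 4) in EAM and 5.44 ± 0.93 (SD, n = 3) in LAD, a 5.27-fold difference (log2 standard error 0.40, adjusted p = 0.00831). This rank depended on the processing. Without background correction the difference of miR-101c was 1.66 (log2) and that of miR-690 was 1.87. In the authors' table that of miR-101c was 1.70 and that of miR-29c-3p was 2.23. miR-101a-3p was 4.36-fold higher, with 8.55 ± 0.16 in EAM and 6.43 ± 1.05 in LAD (adjusted p = 0.00976). The differences of miR-101a-3p and miR-101c were close in the authors' table (1.69 and 1.70) and without scaling (3.45 and 3.49). They were less so with the 75th percentile of detected probes (1.54 and 1.10). Whether the probes tell these 2 names apart was not tested, so they may not be separate measurements. miR-146a-5p, a brake on NF-κB signalling in activated T cells, was 3.97-fold higher, with 9.18 ± 0.07 in EAM and 7.19 ± 1.33 in LAD (adjusted p = 0.0160). Its LAD values were 8.70, 6.21 and 6.66, and its difference was 1.5 (log2) without LAD array 2 and 2.74 without LAD array 1. miR-29c-3p, of a family that restrains interferon-γ production in T cells, was 3.59-fold higher, with 10.60 ± 0.12 in EAM and 8.75 ± 1.27 in LAD (adjusted p = 0.0176), where its values were 10.22, 8.06 and 7.99, and its difference was 2.57 (log2) without LAD array 1.

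The other 8 of the 12 miRNAs with the largest difference toward EAM were miR-690, miR-3473a, miR-3473b, miR-6516-3p, miR-151-5p, miR-219a-5p, miR-1839-5p and miR-203-3p. Of these, miR-690 is on the list of names whose probes resemble fragments of other RNAs or are GC-rich. miR-690 was 4.20-fold, miR-3473a 4.08-fold and miR-3473b 3.33-fold higher, and miR-6516-3p, miR-151-5p, miR-219a-5p and miR-1839-5p were 3.20-, 3.18-, 3.06- and 2.99-fold higher. Of these 4, all but miR-219a-5p were detected on 2 of 3 LAD arrays, so their folds are rough. miR-203-3p, detected on all 4 EAM arrays and no LAD array, was at least 2.88-fold higher in these background-corrected values. Its difference was 0.58 (log2) without background correction and in the authors' table, and 3.33 by total gene signal. With the 75th percentile of all probes it was 0.08 (adjusted p = 0.363). Over 8 alternative sets of values (other background correction, scaling or summary, not independent of each other) it passed in 6. miR-155-5p, which activated T cells induce, was 2.21-fold higher in EAM, with 9.61 ± 0.03 against 8.46 ± 0.83 (adjusted p = 0.0237). The LAD values of miR-155-5p were 9.40, 8.12 and 7.86, so LAD arrays 2 and 3 carried most of its difference. That difference was 1.62 (log2) without LAD array 1 and 0.85 without LAD array 3. miR-150-5p, abundant in resting mature lymphocytes, was 2.67-fold higher, with 12.47 ± 0.05 against 11.05 ± 1.20 (adjusted p = 0.0327); its LAD values were 12.19, 9.79 and 11.18, and its difference was 0.79 (log2) without LAD array 2 and 1.99 without LAD array 1. miR-21a-5p, also induced by activation, did not pass, at 12.55 ± 0.06 in EAM and 11.98 ± 1.04 in LAD (adjusted p = 0.247). LAD array 1 had the highest miR-21a-5p value of all arrays, 13.04, and LAD arrays 2 and 3 had 10.96 and 11.94. Its difference of 0.58 (log2) was 0.063 without LAD array 2 and 1.11 without LAD array 1, where it passed (adjusted p = 0.0280). It also passed toward EAM with median centring (adjusted p = 0.00513), with the 75th percentile of all probes (0.0137) and without scaling (0.00251). Without LAD array 3 the adjusted p was 0.0649 for miR-146a-5p, 0.0706 for miR-29c-3p and 0.0856 for both miR-150-5p and miR-155-5p. Without any single EAM array the calls of miR-150-5p and miR-155-5p ended too, with adjusted p values of 0.0651 to 0.0756 and 0.0520 to 0.0619, and that of miR-29c-3p ended without EAM array 4 (adjusted p = 0.0530). Other processing ended some calls as well. That of miR-150-5p ended with local background and an offset of 50 (adjusted p = 0.0506) and by total gene signal (0.0745). That of miR-155-5p ended by total gene signal (0.0612), and that of miR-146a-5p with the 75th percentile of detected probes (0.0568).

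LAD cells had higher levels of miR-181a-5p, miR-223-3p, miR-376c-3p and miR-3063-3p. miR-181a-5p, which tunes the sensitivity of the T cell receptor and is high in immature T cells, was 9.48-fold higher, with 10.84 ± 1.60 (log2, SD, n = 3) in LAD and 7.60 ± 0.18 (SD, n = 4) in EAM (log2 standard error 0.62, adjusted p = 0.00935). Its values on LAD arrays 1 to 3 were 9.01, 11.97 and 11.54, and its difference was -4.16 (EAM minus LAD, log2) without LAD array 1. miR-223-3p, a miRNA of neutrophils and other myeloid cells, was 3.33-fold higher, with 8.17 ± 0.86 in LAD and 6.43 ± 0.17 in EAM (adjusted p = 0.0103), and its LAD values were 9.16, 7.72 and 7.63. miR-376c-3p, of the imprinted Dlk1-Dio3 cluster, was detected on all 3 LAD arrays and no EAM array and was at least 13.6-fold higher in these background-corrected values (adjusted p = 0.0150). Its LAD values were 7.82, 4.53 and 9.46, and those of miR-3063-3p (adjusted p = 0.0138) were 8.27, 5.15 and 9.68, against 3.99 ± 0.40 in EAM, where 2 of 4 arrays detected it. The differences of miR-376c-3p and miR-3063-3p were -5.21 and -4.98 without LAD array 2 and -2.75 and -2.72 without LAD array 3. They also depended on the background and scaling: without background correction they were -2.24 and -2.40, in the authors' table -1.99 and -2.14, and with the 75th percentile of detected probes, where neither passed, -1.46 and -1.67 (adjusted p = 0.180 and 0.176).

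The other 8 miRNAs with the largest difference toward LAD were miR-181a-1-3p, miR-466f-3p, miR-466h-3p, miR-207, miR-6348, miR-7047-3p, miR-1943-3p and miR-32-3p. miR-181a-1-3p was 5.35-fold higher (adjusted p = 0.0346), with LAD values of 4.42, 8.70 and 7.05. Over the 8 alternative sets of values it passed in 1, with median centring (adjusted p = 0.0123). Its difference was -1.49 (EAM minus LAD, log2) in the authors' table (adjusted p = 0.0610). miR-466f-3p was 5.14-fold and miR-466h-3p 3.64-fold higher, and miR-207, miR-6348, miR-7047-3p, miR-1943-3p and miR-32-3p were 3.19-, 3.12-, 3.05-, 3.04- and 2.95-fold higher. From miR-207 to miR-32-3p, the differences (EAM minus LAD, log2) were -0.85 to -0.995 without background correction, where they passed. With the 75th percentile of detected probes they were -0.40 to -0.85 and did not pass (adjusted p = 0.176 to 0.198). Of the 8, all except miR-181a-1-3p had their lowest LAD value on LAD array 2, as had miR-376c-3p and miR-3063-3p. That was the brightest LAD array, with a 75th percentile of 501 intensity units against 193 and 124 on LAD arrays 1 and 3. An effect of array brightness on these calls stays open. Without LAD array 2 the difference (EAM minus LAD, log2) was -1.43 for miR-181a-1-3p, -3.38 for miR-466f-3p, -2.65 for miR-466h-3p, -2.30 for miR-207 and -2.34 for miR-6348; it was -1.69 for miR-466f-3p without LAD array 3 and -3.57 for miR-181a-1-3p without LAD array 1. Without LAD array 3 the adjusted p was 0.0876 for miR-466f-3p, 0.0830 for miR-466h-3p, 0.0877 for miR-6348, 0.0632 for miR-207 and 0.0554 for miR-32-3p. Without LAD array 1 it was 0.0713 for both miR-466f-3p and miR-6348 and 0.0690 for miR-466h-3p. Without EAM array 4 it was 0.0619, 0.0591 and 0.0613 for miR-466f-3p, miR-6348 and miR-466h-3p, without EAM array 3 it was 0.0571, 0.0551 and 0.0568, and for miR-6348 it was 0.0526 without EAM array 1. For miR-181a-1-3p it was 0.0617 without LAD array 2, 0.113 without LAD array 3 and 0.0643 to 0.0756 without any single EAM array.

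**Figure D2:**
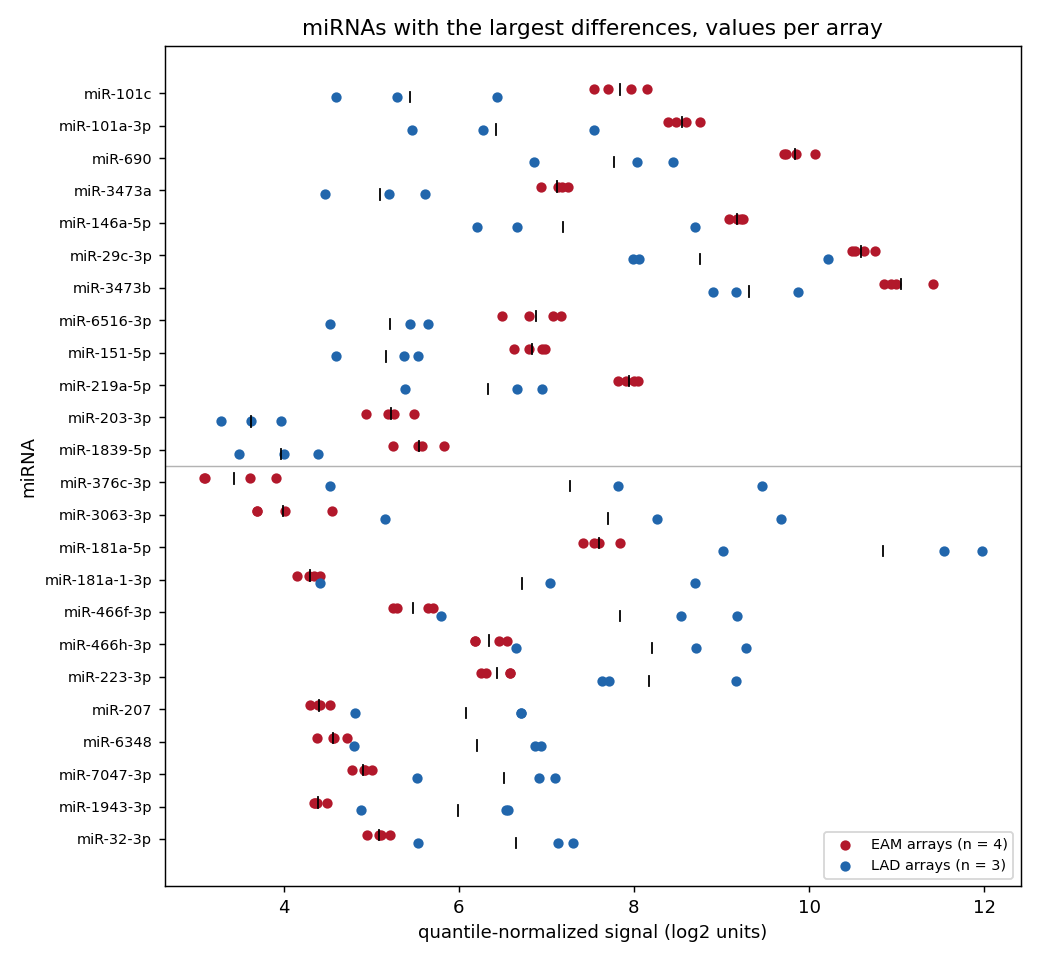
Quantile-normalized log2 signal (horizontal axis) of the 12 miRNAs with the largest difference toward EAM (upper block) and the 12 toward LAD (lower block), with 1 point per array and a tick at each group mean. The 4 EAM values lie close together for each miRNA, while the LAD values of miR-376c-3p range from 4.53 to 9.46.

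By the array design (mm9 assembly, positions counted from 1), the probes of miR-181a-5p match chromosome 1 (139863054 to 139863067, plus strand) and chromosome 2 (38708270 to 38708283, plus strand). Those of miR-223-3p match chromosome X (93438225 to 93438244, plus strand), and those of miR-376c-3p chromosome 12 (110960981 to 110961000, plus strand). Those of miR-101a-3p match chromosome 4 (101019601 to 101019620, minus strand), those of miR-146a-5p chromosome 11 (43187908 to 43187925, minus strand) and those of miR-29c-3p chromosome 1 (196863795 to 196863815, plus strand). In the RefSeq annotation, the miR-151 gene lies within Ptk2, the miR-690 gene within Fgf12, the miR-3473a gene within Syap1, the miR-3063 gene within Igf2bp1, and the miR-466h gene within Sfmbt2.

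In all, 259 of the 423 tested miRNAs passed (limma, adjusted p under 0.05), of which 157 were higher in EAM and 102 in LAD. An unmoderated test with unequal variances passed 0 of the 423. The limma fit takes 1 variance per miRNA for both groups, while the miRNAs above with both SDs given varied more in LAD than in EAM. The standard errors and p values of limma can therefore be too small. With median centring 83 were higher in EAM and 121 in LAD, so that the balance turned, and without scaling 296 and 2 were. The count was 124 to 163 without any single EAM array and 149 without LAD array 3. With a fold of at least 2, 70 were higher in EAM and 42 in LAD. The 4 EAM values lay apart from the 3 LAD values for 239 miRNAs (56.5%). For 1 miRNA taken alone, chance gives 5.71%. The miRNAs share the same 7 arrays, and the filter admitted miRNAs detected in 1 group only, so comparing these shares decides nothing about chance. The median difference over the tested miRNAs was 0.40 (log2) toward EAM after quantile normalization and 1.37 before it. Of the 102 miRNAs higher in LAD, 2 (miR-376c-3p and miR-3063-3p) passed in that direction without scaling between arrays, 94 did not pass and 6 passed as higher in EAM. miR-181a-5p without scaling was at -0.98 (EAM minus LAD, log2; adjusted p = 0.368) and miR-223-3p at -0.06 (adjusted p = 0.905). With scaling to the 75th percentile of probes detected on all arrays, 37 miRNAs were higher in EAM and 6 in LAD. In every one of 9 sets of values (8 with scaling, 1 without), 23 miRNAs were higher in EAM, among them miR-101a-3p, miR-101c, miR-29a-3p, miR-29b-3p, miR-29c-3p, miR-3473a, miR-3473b and miR-690. These sets left out miRNAs at the floor of the 75th-percentile values; with these kept, 11 miRNAs were higher in EAM in every set, among them miR-101c, miR-3473a, miR-3473b and miR-690 but not miR-101a-3p or the miR-29 family. miR-223-3p alone was higher in LAD in all 8 scaled sets, and with floor miRNAs kept 0 were. The 9 sets are not independent checks. Without scaling all 157 calls toward EAM passed, and the authors' table was close to the set without background correction. In each fit that left out 1 array, 114 of the 259 calls were kept, 61 toward EAM and 53 toward LAD.

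**Figure D3:**
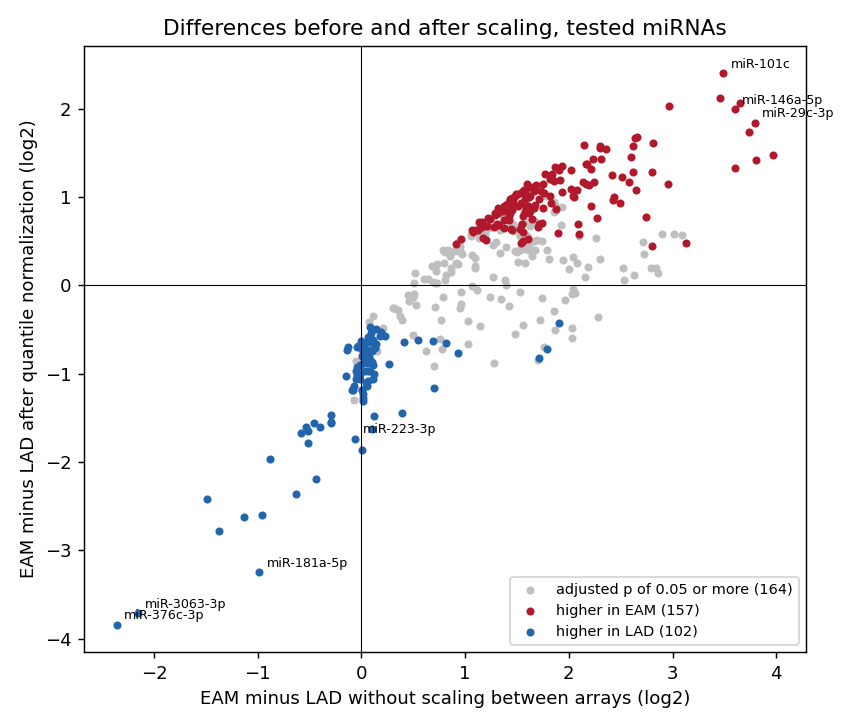
Difference between EAM and LAD (EAM minus LAD, log2) for each tested miRNA without scaling between arrays (horizontal axis) and after quantile normalization (vertical axis), with 1 point per miRNA coloured by its call. The 102 miRNAs higher in LAD after normalization have a median unscaled difference of 0.03, and those of miR-376c-3p and miR-3063-3p are -2.36 and -2.16.

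None of the 14 lists with at least 3 tested members passed (camera with a preset correlation, lowest adjusted p = 0.259; 2 lists at an unadjusted p under 0.05), and none passed with an estimated correlation (lowest adjusted p = 0.898). By limma's fry, which asks whether a list's members move on balance 1 way without comparing them with other miRNAs, 6 lists passed, and 4 passed for change in either direction. These lists stood beside a 3.99-fold lower 75th percentile of signal on the LAD arrays.

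Of the miR-29 family, 3 of the 4 tested members were higher in EAM (4 adjusted over the list alone): miR-29c-3p, miR-29a-3p (13.41 ± 0.08 against 11.94 ± 1.20) and miR-29b-3p (11.73 ± 0.11 against 10.41 ± 1.08). miR-29a-5p had 3.82 ± 0.11 in EAM and was detected on no LAD array (adjusted p = 0.0511; 0.0170 without LAD array 2). With median centring it passed toward LAD, at -0.49 (adjusted p = 0.0399). The family's median difference was 1.40, or 0.995 above that of all miRNAs, and was toward EAM under every scaling (camera adjusted p = 0.320; 0.0284 without LAD array 1). It was carried by LAD arrays 2 and 3, with a median of 0.87 without LAD array 2 and 2.00 without LAD array 1. On LAD array 1, miR-29a-3p, miR-29b-3p and miR-29c-3p differed from the EAM mean by -0.25, -0.14 and -0.38 (log2), on LAD array 2 by -2.65, -2.26 and -2.54, and on LAD array 3 by -1.52, -1.57 and -2.61. The calls of miR-29a-3p and miR-29b-3p ended without LAD array 3 (adjusted p = 0.0877 and 0.104) and without any single EAM array (0.0612 to 0.0711 and 0.0591 to 0.0756), and that of miR-29b-3p also ended without LAD array 2 (0.0514). Without LAD array 1 their differences were 2.08 and 1.92, and without LAD array 2 they were 0.88 and 0.86.

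Of 9 tested miRNAs induced by T cell activation, 3 were higher in EAM (3 adjusted over the list alone) and 6 did not pass: miR-146a-5p, miR-155-5p and miR-7a-5p (7.94 ± 0.08 against 6.65 ± 0.97, adjusted p = 0.0260) passed. Their median difference was 0.58, or 0.17 above all miRNAs (camera adjusted p = 0.460). The call of miR-7a-5p ended without any single EAM array (adjusted p = 0.0522 to 0.0660), and its difference of 1.29 (log2) was 0.73 without LAD array 3.

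Of 19 miRNAs that are high in naive T cells, 10 were higher in EAM, 2 in LAD and 7 did not pass, with the same counts adjusted over the list alone. miR-150-5p, miR-101a-3p and miR-342-5p (4.72 ± 0.10 against 3.72 ± 0.24) were higher in EAM, and the 2 higher in LAD were miR-181a-5p and miR-181b-5p, the latter named after its values were seen. The list's median difference was 0.70, or 0.30 above all miRNAs (camera adjusted p = 0.263). With scaling to the 75th percentile of detected probes the list passed (adjusted p = 0.000404 with the preset correlation), but not with an estimated correlation (adjusted p = 0.336).

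Of the 9 let-7 family members, which are among the most abundant miRNAs of lymphocytes, 4 were higher in EAM (1 adjusted over the list alone) and 5 did not pass. miR-98-5p was 2.99-fold higher (7.34 ± 0.15 against 5.76 ± 1.03), and let-7g-5p was 1.39-fold higher, with 12.94 ± 0.05 against 12.46 ± 0.18. The call of miR-98-5p ended without EAM array 4 (adjusted p = 0.0506), and that of let-7g-5p without any single EAM array (0.0790 to 0.0930) and without LAD array 3 (0.0585). The median difference of 0.45 was 0.04 above all miRNAs, and below them by total gene signal (camera adjusted p = 0.331). With 75th-percentile scaling of detected probes the list passed (adjusted p = 1.37e-05 with the preset correlation), but not with an estimated correlation (adjusted p = 0.336).

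The cluster of miR-17 to miR-92a and its paralogs, which promote lymphocyte proliferation, had 1 of 13 tested members higher in LAD (0 adjusted over the list alone), miR-19b-3p, with 11.77 ± 0.45 in LAD and 11.05 ± 0.07 in EAM (adjusted p = 0.0274). The cluster's median difference was -0.26, toward LAD, and turned toward EAM with median centring, with the 75th percentile of all probes, in the authors' table, without scaling and without LAD array 2 (camera adjusted p = 0.263; 0.0284 without LAD array 1; 0.833 without LAD array 2, with a median of 0.16). Of 6 tested members of the miR-15 and miR-16 family, miR-195a-5p was higher in EAM and miR-15a-5p in LAD (list alone: 1 in EAM, 0 in LAD), and 4 did not pass. The family's median was -0.22 and turned toward EAM with both 75th-percentile scalings, with median centring, without scaling and, at 0.10, without LAD array 2 (camera adjusted p = 0.481; 0.936 without LAD array 2). Without scaling, miR-15a-5p and miR-19b-3p differed by 1.71 and 1.79 (log2) toward EAM (adjusted p = 0.0528 and 0.0380), against a median of 1.37 over all tested miRNAs. Both calls toward LAD ended without any single EAM array (adjusted p = 0.0642 to 0.10 and 0.0636 to 0.0657) and without LAD array 3 (0.118 and 0.0774), and that of miR-15a-5p also without LAD array 2 (0.0701, at -0.54). Without LAD array 1, miR-15b-5p, miR-16-5p, miR-20a-5p, miR-20b-5p and miR-92a-3p passed toward LAD (adjusted p = 0.0138, 0.0470, 0.0230, 0.0104 and 0.0280).

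None of the 5 tested members of the miR-23, miR-27 and miR-24 clusters passed, with values such as 9.17 ± 0.03 in EAM and 8.92 ± 0.38 in LAD for miR-24-3p (0 adjusted over the list alone; median difference 0.30, camera adjusted p = 0.748). Without LAD array 2, miR-23b-3p, miR-27a-3p and miR-27b-3p passed toward EAM (adjusted p = 0.0190, 0.0405 and 0.000135) and the median was 0.54; without LAD array 3 the median was 0.033 and the camera direction turned. Of 6 tested miRNAs linked to Th17 cells, miR-155-5p was higher in EAM (0 adjusted over the list alone; camera adjusted p = 0.912). The Th17-linked median, 0.17, was toward EAM but opposite in sign to the camera direction, and turned toward LAD with the local-background correction, with the 75th percentile of detected probes, floor miRNAs kept or not, with detection on all 7 arrays (-0.21), without LAD array 1 (-0.098) and without LAD array 3 (-0.0056). Of 6 tested miRNAs linked to regulatory T cells, miR-146a-5p and miR-155-5p were higher in EAM (2 adjusted over the list alone), and the median of 0.16 was again opposite in sign to the camera direction (adjusted p = 0.845) and turned to -0.056 without LAD array 2. miR-721, on which a later report of the same group centres, was detected on 0 arrays, with 3.46 ± 0.14 in EAM and 3.11 ± 0.11 in LAD.

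Of 3 tested members of the Dlk1-Dio3 cluster, miR-376c-3p and miR-668-3p (5.41 ± 0.32 in LAD against 4.49 ± 0.04 in EAM) were higher in LAD. miR-487b-3p, detected on no LAD array, was at least 1.84-fold higher in EAM in the background-corrected values. Adjusted over the list alone the counts were the same (camera adjusted p = 0.414). The difference of miR-487b-3p was 0.30 (log2) without background correction and in the authors' table, and 0.11 with median centring (adjusted p = 0.632). It passed in 5 of the 8 alternative sets of values. Of 37 tested miRNAs of the Sfmbt2 intron, 7 were higher in EAM, 10 in LAD and 20 did not pass (list alone: 4 in EAM, 7 in LAD). miR-467e-5p was 2.25-fold higher in EAM (a difference of 1.17, and 0.76 without LAD array 3), and miR-669a-3-3p was 2.94-fold higher in LAD (5.94 ± 0.998 against 4.39 ± 0.20). The call of miR-467e-5p ended without EAM array 4 (adjusted p = 0.0506) and that of miR-669a-3-3p without LAD array 3 (0.0609), while that of miR-487b-3p ended without EAM array 3 or 4 (0.0606 and 0.0644) and without LAD array 1 or 3 (0.0594 and 0.0701). The Sfmbt2 median of -0.25 turned toward EAM with the 75th percentile of all probes and without scaling (camera adjusted p = 0.259; 0.00172 without LAD array 2, with a median of -0.89). With 75th-percentile scaling of detected probes the Sfmbt2 list passed (adjusted p = 0.0343), but not with an estimated correlation (adjusted p = 0.721).

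Markers of other cell types that a lymph node sample could hold were examined beside these. Epithelial miRNAs were higher in EAM for 4 of 5 tested members (4 adjusted over the list alone): miR-203-3p, miR-200a-3p (at least 2.09-fold in background-corrected values, no LAD array), miR-141-3p and miR-200b-3p. The last 2 were detected on 1 of 3 LAD arrays, so no fold is given. With median centring miR-200a-3p was 0.39 (adjusted p = 0.0575), miR-141-3p 0.14 (0.466) and miR-200b-3p -0.06 (0.725), while miR-203-3p passed. Without background correction miR-200a-3p was 0.44. Over the 8 alternative sets of values, miR-203-3p passed in 6, miR-200a-3p and miR-200b-3p in 5 and miR-141-3p in 4. The call of miR-141-3p ended without EAM arrays 2, 3 or 4 (adjusted p = 0.0589, 0.0650 and 0.0756) and without LAD array 1 or 3 (0.0841 and 0.0884), and that of miR-200b-3p without EAM array 3 or 4 (0.0538 and 0.0604). The epithelial median was 0.87 (camera adjusted p = 0.259). It was 0.31 without background correction and in the authors' table, 0.14 with median centring, 0.047 with the 75th percentile of all probes and 1.80 by total gene signal. Of 3 tested B cell markers, miR-28a-5p, detected on 1 LAD array, and miR-28a-3p, on 0, were higher in EAM (2 adjusted over the list alone; camera adjusted p = 0.460), and the list's median of 0.66 turned toward LAD with median centring. The call of miR-28a-5p ended without EAM array 4 or LAD array 3 (adjusted p = 0.0552 and 0.0599), and that of miR-28a-3p without EAM arrays 2, 3 or 4 (0.0522, 0.0568 and 0.0605) or LAD array 1 (0.0506). Over the 8 alternative sets of values miR-28a-5p passed in 7, and miR-28a-3p in 1, without scaling. miR-28a-3p was 0.14 (log2) in the authors' table (adjusted p = 0.0744) and -0.11 with median centring (0.535). The myeloid miR-223-3p was the 1 tested member of its list. The red-cell miR-451a had 6.57 ± 0.29 in EAM and 6.71 ± 0.90 in LAD (adjusted p = 0.760), and turned toward EAM with the 75th percentile of all probes, without scaling and without LAD array 1 (0.37). The stromal miR-125b-5p had 4.20 ± 0.15 and 4.13 ± 0.02 (adjusted p = 0.685), and with median centring it passed toward LAD (-0.68, adjusted p = 0.00776). Endothelial, muscle and liver miRNAs had 0 tested members. Of 22 tested names whose probes resemble fragments of other RNAs or are GC-rich, 7 were higher in EAM, among them miR-690, and 2 in LAD. Adjusted over the list alone, 3 were higher in EAM and 0 in LAD. The list's median of 0.20 (camera adjusted p = 0.817) turned to -0.01 with the 75th percentile of detected probes and with detection on all 7 arrays.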

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

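The tests on unscaled signal, spiked-in controls, probes resembling other RNAs, activation and scaling, and the count over splits, were chosen only after the results were seen; those on GC share and on unexamined miR-181 members were chosen before. The 3 values of EAM array 1 given first lay far from the other EAM arrays, out of 72 groups of values checked, of which chance marks about 1 in 20; 2 kinds of value, the share of spots marked as outliers and the number well above background, were added to the check after they were seen.

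On EAM array 1, miR-28a-3p had 3.22 against 3.55 to 3.58 on the other EAM arrays, a gap of 0.912 of the range. EAM array 1 had 1100 miRNAs with a probe well above background against 536 to 606 (0.876 of the range), and 4.90% of its spots were marked as outliers against 2.74% to 2.93% (0.915 of the range). Outside the tests, 130 miRNAs were detected on at least 1 array.

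The LAD arrays had a lower overall signal. Failed hybridisation would have lowered the spiked-in RNAs as well, but their mean was 0.23 (log2) higher in LAD. Controls of labelling and of hybridisation were not examined apart, so the mean does not test failed labelling on its own. Another set of control probes, whose targets the files do not give, was 1.86 (log2) lower in LAD, and decides nothing without a known target. A loss of miRNAs alone, with other small RNA fragments kept, is argued against by the 22 tested names whose probes resemble tRNA, rRNA or GC-rich sequence, which had an unscaled median difference of 1.55 toward EAM, close to the 1.37 of all tested miRNAs. This holds only as far as these names measure such fragments, which was not shown. The detection filter also favoured EAM, with 49 miRNAs detected on all EAM and no LAD arrays and 4 the other way. RNA amount or quality that differed between samples and a lower small RNA content of the LAD cells both stay open, and were not tested.

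The 102 miRNAs higher in LAD after normalization may include probes whose signal does not follow the miRNA level of the array and which scaling lifts on dim arrays. Their median unscaled difference was 0.031 (log2). The slope of their unscaled signal on the 75th percentile of the array within groups was 0.039. Both values lay below those of the other tested miRNAs, 1.54 and 0.614, but the set was chosen by scaled differences, which both measures follow (rank correlations 0.778 and 0.449 over the tested miRNAs). They therefore decide neither this account nor a higher level in LAD cells for the set as a whole, and both stay open. Their probes had 8.02 percentage points more GC (60.9% against 52.9%; permutation p = 1e-05, the smallest that the permutations can give), so GC-rich probes stay a candidate explanation. Of the set, miR-376c-3p and miR-3063-3p were higher in LAD without scaling too (-2.36 and -2.16, EAM minus LAD, log2), so lifting by scaling alone does not account for them. Their normalized LAD values were highest on the dimmest LAD array and lowest on the brightest, so an effect of array brightness stays open for them as well.

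On LAD arrays 2 and 3, miR-181a-5p and miR-181b-5p were high while miR-150, miR-29 and miR-146a were low; on LAD array 3, miR-181c-5p and miR-181d-5p were only 0.42 and 0.52 (log2) above the EAM mean. Scaling between arrays is argued against, since the unscaled difference of miR-181a-5p from miR-150-5p within an array, on the lower of these 2 arrays, was 4.85 (log2) above the highest EAM array. miR-155-5p and miR-21a-5p, which activation induces, were below the EAM mean on both arrays, the closest by -0.61. miR-146a-5p was too, but belongs to the pattern itself. But miR-155-5p and miR-21a-5p also stand on the list of miRNAs high in mature T cells given below. Immature cells in these samples could lower them too, so the values do not decide on T cell activation. No cells of healthy mice were measured either. Immature CD4+CD8+ thymocytes, which selection for CD4 would not remove, could be among the cells: miR-181c-5p, the only detected one of 6 family members not examined before, was higher on LAD array 2 than on each EAM array (1 of 1) but level with the highest EAM array on LAD array 3 (7.13 on both), which is too few to decide. On both arrays 7 of 7 miRNAs listed as high in thymocytes were above the EAM mean, from miR-181b-5p (27.6-fold) and miR-128-3p (17-fold) to miR-92a-3p (1.66-fold) on LAD array 2, and 0 of 8 listed as high in mature T cells. Those lists were drawn up after the pattern was seen and so decide nothing. The model and the day stay open, untested.

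Of the 35 splits of the 7 arrays into 4 and 3, 1, the real one, called as many as 259 miRNAs, and the highest other split called 0. Every other split puts EAM and LAD arrays into 1 group, which widens the spread within groups and favours few calls. With 35 splits no two-sided exact permutation p can be below 0.0571, so the splits do not exclude chance for the count.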

How the results depend on the processing

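The fits without 2 LAD arrays, and those with 75th-percentile scaling that leave out miRNAs at the floor on all 7 arrays, were chosen only after the results were seen. The count of 259 (a share of 0.612 of the 423 tested) stayed within 1.5 times (204 to 349) with no background correction, local background with an offset of 50, median centring, no scaling, total gene signal, the authors' table, a filter of detection on at least 1 array, trended robust variance, array weights, and a random replicate block. Without LAD arrays 1 and 3 it was 194, and without 2 and 3 it was 386; these fits have 1 LAD array, assumed to vary like the EAM arrays, and say nothing about its spread. It was 43 (share 0.178; 37 in EAM, 6 in LAD) and 113 (0.347, 99 and 14) with 75th-percentile scaling of detected and of all probes, and 19 (0.0449, 18 and 1) and 82 (0.194, 75 and 7) with miRNAs at the floor kept. Of the 423 miRNAs, 241 were above the floor with detected probes, and 97 were at it with all probes, so fewer were tested or could vary. It was 507 (0.270 of 1881 tested) with no filter, 137 (0.546 of 251 tested) with detection on all 7 arrays, 112 (0.265) with a fold of at least 2, and 0 by an unmoderated unequal-variance test, against 289 at an unadjusted p under 0.05 in limma; the cause was not tested. The share was 0.290 to 0.832 in the fits without 1 array, lowest without EAM array 4 (124 of 428 tested) and highest without LAD array 2 (of 458 tested), whose count was within 1.5 times, as was the count of 177 without LAD array 1. Replicate numbers did not pair the samples, with correlations of 0.18, -0.10 and -0.25 between same-numbered arrays and 2 of 6 arrays closest to their own number. As a fixed block they gave 37 calls (0.0864) on 6 arrays, against 124 unblocked on the same arrays, and as a random block 249 on 7. The difference in detected miRNAs of 114 was 313 by a probe well above background (179 without EAM array 1), and 97.5 to 118 without any 1 array other than LAD array 2, and larger than 118 without that array.

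Of 1808 values of 67 named miRNAs over the alternatives, 1324 kept direction and side of the threshold, 373 no longer passed, 52 passed only there and 59 changed sign, some of which passed in neither fit. Of the 59, 9 passed in the new direction: miR-15b-5p, miR-16-5p, miR-19b-3p, miR-92a-3p, miR-451a and miR-669f-3p without scaling, miR-125b-5p and miR-29a-5p with median centring, and miR-21a-5p without LAD arrays 2 and 3. Without scaling, where the median of all miRNAs was 1.37, miR-15a-5p was 1.71, miR-15b-5p 2.03, miR-16-5p 2.28, miR-19b-3p 1.79, miR-20a-5p 1.76, miR-20b-5p 1.70, miR-92a-3p 2.03, miR-451a 1.24, miR-669f-3p 0.93 and miR-466h-3p 0.0039 (EAM minus LAD, log2). With median centring miR-15a-5p was 0.43, miR-15b-5p 0.76, miR-16-5p 1.01, miR-19b-3p 0.51, miR-20a-5p 0.48, miR-20b-5p 0.43, miR-92a-3p 0.76, miR-96-5p -0.12, miR-125b-5p -0.68, miR-200b-3p -0.060, miR-28a-3p -0.11, miR-29a-5p -0.49 and miR-6238 -0.054. With the 75th percentile of all probes, floor miRNAs kept or not, miR-15a-5p was 0.76, miR-15b-5p 1.07, miR-16-5p 1.33, miR-19b-3p 0.83, miR-20a-5p 0.81, miR-20b-5p 0.75, miR-92a-3p 1.08 and miR-451a 0.43; with that of detected probes, likewise, miR-15b-5p was 0.042, miR-16-5p 0.30, miR-92a-3p 0.051 and miR-23b-3p -0.074. With array weights miR-21a-5p was -0.31 and miR-24-3p -0.021. Without LAD arrays 2 and 3, miR-21a-5p was -0.49, miR-24-3p -0.12, miR-15b-5p 0.025, miR-16-5p 0.069 and miR-20b-5p 0.0038; without 1 and 3, miR-23b-3p was -0.18, miR-27a-3p -0.13, miR-27b-3p -0.26 and miR-451a 0.20. Over the fits without 1 array miR-451a ranged from -0.48 to 0.37. For these changes of sign the cause was not tested.

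List p values, adjusted, moved past 0.05 in these settings; the cause was not tested. With the 75th percentile of detected probes they were 0.0343 for activation-induced, 0.000404 for naive-high, 1.37e-05 for let-7, 0.0223 for miR-29 and 0.0343 for Sfmbt2, but with an estimated correlation none passed (0.365, 0.336, 0.336, 0.365 and 0.721 in this order). With floor miRNAs kept, 0.0344, 5.2e-06, 1.13e-07, 0.0116 and 0.0116, and 0.0304 for regulatory T cells, whose direction reversed. With detection on all 7 arrays, naive-high had 0.0300. By fry, naive-high, let-7, miR-29, Dlk1-Dio3 and B cell had 0.0440 and epithelial 0.0195; in either direction, naive-high and epithelial had 0.0107, let-7 and the names resembling other RNAs 0.0313. The camera direction turned, without passing, in these settings. It did so with the 75th percentile of detected probes for Th17-linked (0.845), regulatory T cells (0.0502) and miR-15 and miR-16 (0.771), with floor miRNAs kept for Th17-linked (0.932), miR-15 and miR-16 (0.774) and the names resembling other RNAs (0.940), and without scaling for Th17-linked (0.803), regulatory T cells (0.393) and miR-15 and miR-16 (0.850). For Th17-linked and regulatory T cells it also turned in the authors' table (0.805 and 0.683), with detection on all 7 arrays (0.755 and 0.499) and by fry (0.509 and 0.401), and for regulatory T cells with the fixed block (0.917). It turned without LAD array 2 for Th17-linked, miR-15 and miR-16, and the cluster of miR-17, without LAD array 3 for the clusters of miR-23, miR-27 and miR-24, and without LAD array 1 or EAM array 3 for regulatory T cells. Over the fits without 1 array, Th17-linked ranged from 0.695 to 0.947, regulatory T cells from 0.696 to 0.888, miR-15 and miR-16 from 0.208 to 0.936, the clusters of miR-23, miR-27 and miR-24 from 0.457 to 0.921, miR-29 from 0.0284 to 0.457, the cluster of miR-17 from 0.0284 to 0.833 and Sfmbt2 from 0.00172 to 0.414.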

Other observations

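Other miRNAs showed the same direction as those above and were named after their values were seen. The miR-378 family, encoded in part within genes of energy metabolism, was higher in EAM for each of 5 members examined: miR-378a-3p 2.73-fold (7.58 ± 0.17 in EAM, n = 4, against 6.13 ± 0.77 in LAD, n = 3), miR-378a-5p 2.60-fold, miR-378b 2.33-fold, miR-378c 2.52-fold and miR-378d 2.44-fold. Whether the probes tell the members of this family apart was not tested, so these may not be 5 separate measurements. miR-140-3p was 2.12-fold and miR-140-5p 1.95-fold higher. miR-378a-3p, miR-378b, miR-378d, miR-140-3p and miR-140-5p were higher in EAM in all 9 sets of values that left out miRNAs at the floor, and all of these but miR-140-5p with floor miRNAs kept. Detected on all 3 LAD arrays and no EAM array were miR-376c-3p and 3 miRNAs of low signal, miR-7057-3p, miR-5127 and miR-7005-3p, at least 1.61-, 1.63- and 1.39-fold higher.

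miR-376b-3p, outside the tests, differed among the EAM arrays, with 7.76 and 7.81 on EAM arrays 1 and 2, 4.90 on array 3 and 3.04 on array 4. miR-466o-3p had 6.12, 6.01, 3.65 and 3.38 on the same arrays.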
